A study of Mus musculus with 6 samples.

How the data were processed

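RNA-seq was used to measure gene expression in 6 mouse samples, 3 labelled Control and 3 labelled Model. The series describes the model as ligation of the inferior vena cava (IVC), the large vein that returns blood from the lower body, with vein and thrombus collected together 24 h later. The labels give "thrombus" as the tissue of all 6 samples and do not say what was done to the Control animals. Samples were grouped by their titles. The labels do not say whether samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

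Per the labels' protocols, ribosomal RNA was removed from total RNA, libraries were made with a low-input kit and read in pairs on a NovaSeq 6000 instrument, and adapters and poor-quality reads were removed with cutadapt 1.9.3. The submitters' processing notes name STAR 2.5.1b, edgeR 3.16.5 and the mouse build mm10. The counting tool, the gene annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and near-identical genes such as the globins, Saa1 and Saa2, or Hspa1a and Hspa1b may have shared reads. Their single values are uncertain.

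The deposited table holds raw counts per gene for the 6 samples, per the file headers, and these counts were used as deposited. It also holds 6 per-sample columns of normalized values, which were not used here. The table lists 17761 genes, each with at least 1 count over the 6 libraries and each given the biotype protein coding in the table itself. Long non-coding RNAs (lncRNAs), named in the series title, were therefore not analysed here as a class. At least 1 row lies at an lncRNA locus although the table lists it as protein coding. The planned count of changed lncRNAs could not be run, and the planned count of changed protein-coding genes is identical to that of all changed genes. A symbol is shared by more than 1 row for 29 symbols, 60 rows in all, and rows were kept apart by gene identifier. Gene positions come from GENCODE release M21 on GRCm38, the assembly that mm10 names. That release held 17555 of the identifiers, and 17225 were protein coding in it.

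Total counts per library were 36640756, 38118463 and 31924426 in Control 1 to 3 and 26924668, 28193281 and 25336173 in Model 1 to 3. A count of 0 in a library allows up to 3 counts, which is between 0.079 and 0.118 CPM (a gene's counts scaled to the usual common library total). This floor covers counting error only, since the reads carry no molecular identifiers that the labels mention. No 2 libraries were duplicates of each other. Their counts differed by far more than sampling noise in every pair.

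Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 13907 genes, and libraries were scaled by the trimmed mean of M values (TMM). Model was compared with Control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, with an adjusted p threshold of 0.05. The standard error (SE) of a log2 fold change was derived from the fold change and its F statistic. Levels are TMM-scaled CPM, given as mean ± SD of 3 libraries. In addition, 39 gene lists were fixed before the data were examined. They cover cell types of blood, vein and neighbouring tissue, haemostasis, inflammation, matrix, stress and RNA quality. Lists with at least 3 tested members, 37 in all, were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists. For each list the members past the gene test were counted, adjusted over all genes and adjusted over the list alone.

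The rule for named genes was also fixed before the data were examined. It takes the 10 genes with the largest rise and the 10 with the largest fall among those past the test, with no overlap between the groups and a mean of at least 8 CPM. Predicted gene models and antigen receptor segments were left out. It adds up to 2 members of each list in each direction and 17 genes of haemostasis, inflammation and cell type named in any case. It gave 78 genes, and the texts name fewer. Members outside the rule are named where a count was 5 or fewer, and were chosen after their values were seen.

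The alternatives were leaving out each library in turn, the replicate number as a block, RLE and upper-quartile scaling, no filter, a stricter filter with a minimum count of 100, DESeq2 1.42.0, limma-voom, a required log2 fold change of at least 1, camera with an estimated correlation, and fry in place of camera. After the data were seen, a fit without both Control 1 and Model 2 was added, because Control 1 lay apart from the other libraries and Model 2 held high levels of liver transcripts. The gene test was tested on simulated counts for 13907 genes with the real means, depths and dispersions. It called 43.0% of 100 genes changed 4-fold and 69.0% of 100 changed 16-fold in the right direction, and 1 unchanged gene. The changes were planted only in genes above a set mean count, higher than the filter requires. The shares over all tested genes may therefore be lower. Camera called 20 of 20 simulated lists that had been raised and 0 unchanged lists. With an estimated correlation it also called 20 raised lists. The simulated genes varied independently of each other. In the data the estimated correlation was 0.401 for the neutrophil list, 0.445 for the platelet list and 0.733 for the erythroid list. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes. Pathway annotations in the deposited table were tested for over-representation with a hypergeometric test in scipy 1.17.1, as a step chosen after the data were seen. On simulated sets of genes this test found the planted pathway in 20 of 20 draws, and it called a pathway in 0 of 20 random draws. Each planted pathway was given 20 members, more than most pathways called in the data held, and the random genes were drawn independently. The draws therefore cannot show how often smaller overlaps are missed or how often pathways of correlated genes are called.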

Results

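Expression of 17761 genes that the deposited table lists as protein coding was measured in 3 Control and 3 Model samples of mouse tissue. The Model samples were IVC taken with its thrombus 24 h after ligation. The labels do not say what was done to the Controls. The libraries held 25336173 to 38118463 counts, and the Model libraries were the shallower ones. The comparison of Model with Control asks which transcripts differ in ligated vein taken with its thrombus. It cannot separate the thrombus from the ligation and the surgery, or cells of the thrombus from the vein wall. Correlations of log2 CPM ranged from 0.793 to 0.904 within groups and from 0.706 to 0.817 between groups. Control 1 lay apart from the other 5 libraries on the first principal component, which held 36.9% of the variance, and Model 1 on the second, which held 25.3%.

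Ligated veins with their thrombus held far more transcripts of many neutrophil and platelet genes and of some cytokines, and fewer of some lymphocyte genes. Il6, a cytokine of acute inflammation, was at 0.104 ± 0.0737 CPM in Control and 17.4 ± 8.92 CPM in Model (SD, n = 3 each), a log2 fold change of 7.34 (SE 1.37). Thbs1, which encodes the matrix glycoprotein thrombospondin 1, rose from 275 ± 34.2 to 2785 ± 612 CPM. Fcer2a, the low-affinity IgE receptor of B cells, fell from 193 ± 55.3 to 15.7 ± 5.27 CPM. In all, 377 genes were higher and 189 lower in Model among 13907 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 368 and 188 of them differed at least 2-fold. An unadjusted p under 0.05 was found for 2200 genes. DESeq2 called 639 higher and 578 lower genes, and the test without a filter 642 and 469, so the number of lower genes and its balance with the higher ones depend on the method. The groups did not overlap at 23.5% of tested genes, against 10% by chance. Without Model 1 the count fell from 566 to 317 genes, and without Control 1 and Model 2 together to 285. The lower genes fell to 92 without Control 1 and 96 without Model 1.

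**Figure D1:**
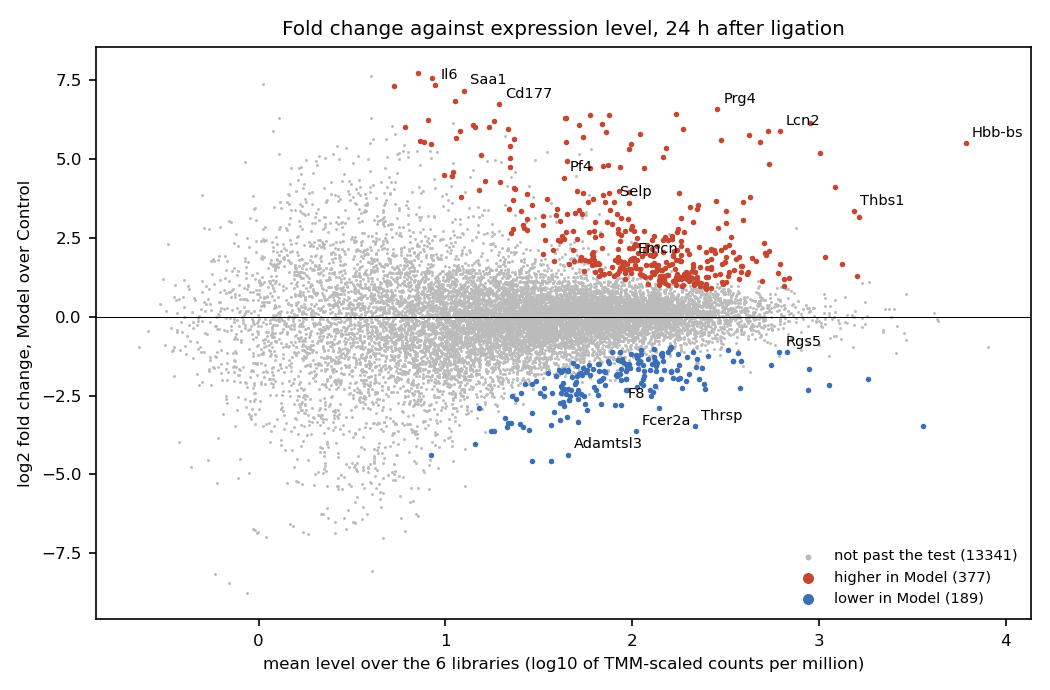
Log2 fold change of Model over Control against the mean level over the 6 libraries (log10 of TMM-scaled CPM), 1 point per tested gene. Red points are the 377 genes higher in Model, blue points the 189 lower, and grey points did not pass edgeR's quasi-likelihood test at an adjusted p of 0.05.

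The genes with the largest rise under the naming rule included Csf3, Il6, Saa1, Cd177, Prg4, Retnlg, Mmp8, Ptx3 and Timp1, with log2 fold changes from 7.55 to 6.30. Csf3 (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629 of GRCm38) encodes the growth factor of neutrophils and rose by 7.55 (SE 1.53, adjusted p = 0.0148). Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), an inhibitor of matrix metalloproteinases, rose by 6.30 (SE 0.56, adjusted p = 6.00e-05). Ptx3 (ENSMUSG00000027832, chromosome 3, 66219910 to 66225805), a secreted pattern-recognition protein, rose by 6.39 (SE 0.60, adjusted p = 9.36e-05). Prg4, which encodes the lubricant lubricin, rose by 6.57 (SE 0.75) to between 168 and 1290 CPM in the Model libraries. Saa1, a serum amyloid A gene that may share reads with Saa2, rose by 7.16 (SE 1.11). Il6 and Csf3 lost their calls without Model 3 (adjusted p = 0.0543 and 0.127). With limma-voom the calls of Csf3, Il6, Saa1, Prg4 and Mmp8 were lost (adjusted p = 0.133, 0.0917, 0.0703, 0.0592 and 0.0604).

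The 10 genes with the largest fall were Ccr9, Apol7c, Ldoc1l, Adamtsl3, Gbp2b, Izumo4, Fcer2a, Col6a6, Srpk3 and Shank1, with log2 fold changes from -4.59 to -3.49. Adamtsl3 (ENSMUSG00000070469, chromosome 7, 82335694 to 82614450 of GRCm38), a secreted ADAMTS-like matrix protein, was at 86.1 ± 51.7 CPM in Control and 4.16 ± 0.931 CPM in Model (log2 fold change -4.37, SE 0.53, adjusted p = 5.51e-04). Fcer2a (ENSMUSG00000005540, chromosome 8, 3681737 to 3694175) had a log2 fold change of -3.62 (SE 0.36, adjusted p = 1.37e-04). Ccr9, a chemokine receptor of lymphocytes, had a log2 fold change of -4.59 (SE 1.04, adjusted p = 0.0271), which was -2.28 without Control 1. That library held 144 CPM of Ccr9 against 10.1 and 12.1 CPM in Control 2 and Control 3. Without Control 1 the calls of Ccr9, Apol7c, Ldoc1l, Gbp2b, Izumo4, Srpk3 and Shank1 were lost, with adjusted p from 0.0715 for Ldoc1l to 0.417 for Ccr9. Col6a6 lost its call without Control 3 (adjusted p = 0.109) or Model 1 (adjusted p = 0.0877). Ccr9 and Apol7c lost theirs also without Model 1 (0.103 and 0.107) or Model 3 (0.0658 and 0.0567), Izumo4 also without Model 3 (0.0543), and Srpk3 also without Model 1 or Model 2 (0.0844 and 0.0636). Ldoc1l lost its own without any 1 library (0.0715 to 0.190), and Gbp2b without any 1 library but Control 2 (0.0514 to 0.188). With limma-voom only Fcer2a of these 10 genes kept its call, and Adamtsl3 had an adjusted p of 0.0731.

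Most tested genes of neutrophils, platelets and red cells were higher in Model. Of 16 tested neutrophil genes, 12 rose and none fell (14 adjusted over the list alone), with a median log2 fold change of 5.97. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), a calcium-binding protein abundant in neutrophils, went from 17.9 ± 11.3 to 1047 ± 645 CPM, and Cd177, a neutrophil surface protein, rose by 6.73 (SE 0.85). Of 19 platelet and megakaryocyte genes, 15 rose (17 adjusted over the list alone), median 3.94, among them the platelet chemokine Pf4 with 4.40 (SE 0.50) and the collagen receptor gene Gp6 with 5.65 (SE 1.09). Of 10 erythroid genes, 6 rose (8 adjusted over the list alone), median 4.86. The beta-globin gene Hbb-bs went from 265 ± 41.0 to 11930 ± 9038 CPM. Its reads may be shared with Hbb-bt. By camera the neutrophil list had an adjusted p of 2.48e-20 (adjusted p = 0.175 with an estimated correlation), the platelet list 2.48e-20 (adjusted p = 0.187 with an estimated correlation) and the erythroid list 6.02e-10 (adjusted p = 0.234 with an estimated correlation). Without Model 1 the platelet count fell to 9 and the call of Gp6 was lost (adjusted p = 0.121).

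**Figure D2:**
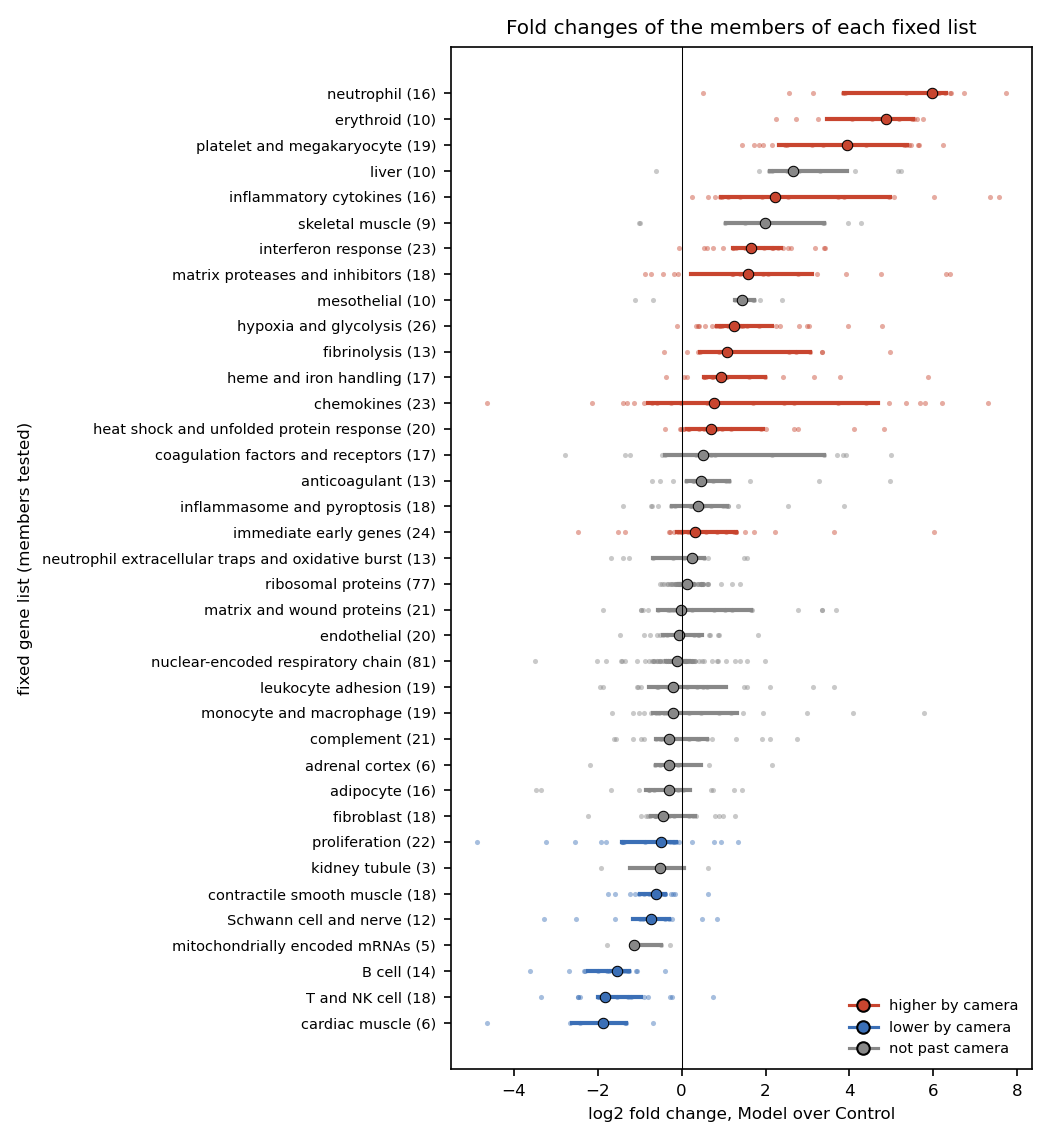
Log2 fold changes of Model over Control for the tested members of the 37 fixed lists with at least 3 tested members. Small points are genes, thick bars the quartiles and large points the medians, red where camera called the list higher, blue where lower and grey where it called neither. Medians ran from 5.97 for neutrophil genes to -1.88 for cardiac muscle genes.

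Some lymphocyte genes were lower in Model. Of 14 tested rows of B cell genes, 6 fell and none rose (11 adjusted over the list alone), with a median log2 fold change of -1.55. Besides Fcer2a, the complement receptor gene Cr2 had a log2 fold change of -2.31 (SE 0.43) in 1 of the 2 rows that carry this symbol. Both rows were counted in the list. Of 18 T and NK cell genes, 6 fell and none rose (10 adjusted over the list alone), median -1.83. Bcl11b, a transcription factor of T cells, had a log2 fold change of -2.47 (SE 0.50) and the CD8 chain gene Cd8b1 one of -2.42 (SE 0.55). By camera the B cell list had an adjusted p of 5.61e-09 (adjusted p = 0.175 with an estimated correlation) and the T and NK cell list 8.35e-07 (adjusted p = 0.303 with an estimated correlation). The T and NK cell count fell to 1 without Control 1, 1 without Model 1 and 3 without Model 3, and the B cell count to 3 without Control 1. Bcl11b and Cd8b1 lost their calls without Control 1 (adjusted p = 0.0745 and 0.132) and without Model 1 (0.0704 and 0.0967), and Cd8b1 also without Model 3 (0.0779).

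Of 19 monocyte and macrophage genes, 4 rose and none fell (4 adjusted over the list alone), with a median log2 fold change of -0.21. Chi3l3, which encodes a chitinase-like protein, rose by 5.78 (SE 0.59) and Arg1, arginase 1, by 4.08 (SE 1.02). The others were Cd14, from 14.1 to 112 CPM, and Plac8 with 1.46, both outside the naming rule and chosen after the values were seen. Camera did not call the list (adjusted p = 0.344), and its mean and test were positive while its median was negative. The count was 2 without Control 3, 1 without Model 1, 2 without Model 2 and 2 without Model 3. Arg1 lost its call in each of those 4 cases (adjusted p = 0.0848, 0.0655, 0.238 and 0.0550).

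Few genes of the vein wall passed the test, but only 4.07% of all tested genes did, so these counts do not set the wall apart. Of 20 endothelial genes, 1 rose and none fell (1 higher and 1 lower adjusted over the list alone). It was Emcn, the endothelial sialomucin endomucin, with 1.82 (SE 0.32, adjusted p = 0.00659). Pecam1, which encodes the endothelial adhesion molecule CD31, was at 512 ± 5.92 CPM in Control and 501 ± 159 CPM in Model (log2 fold change -0.03, SE 0.26, adjusted p = 0.979), and its sign was positive without Model 2 or Model 3. Of 18 contractile smooth muscle genes, 1 was lower (4 adjusted over the list alone), Rgs5 with -1.11 (SE 0.27, adjusted p = 0.0374). Acta2, smooth muscle actin, had a log2 fold change of -0.90 (SE 0.41, adjusted p = 0.302). Of 18 fibroblast genes, 1 fell (2 adjusted over the list alone), the collagen gene Col14a1 with -2.23 (SE 0.34). Camera called the smooth muscle list lower (median -0.61, adjusted p = 4.88e-04, adjusted p = 0.379 with an estimated correlation) and neither the endothelial list (median -0.05, adjusted p = 0.977) nor the fibroblast list (median -0.45, adjusted p = 0.509). The endothelial mean (0.03) and test were positive against the negative median. The call of Rgs5 was lost without Control 1, Control 2 or any 1 of the 3 Model libraries, with adjusted p from 0.0640 to 0.142. The smooth muscle count was 0 without Control 1, Control 2, Model 1 or Model 3, and 2 without Control 3 or Model 2.

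Markers of tissue around the vein were uneven between libraries. Of 16 adipocyte genes, 2 were lower and none higher (3 lower and 1 higher adjusted over the list alone): Thrsp, a regulator of fat synthesis, with a log2 fold change of -3.46 (SE 0.48), and Adrb3, the beta-3 adrenergic receptor of fat cells, with -3.34 (SE 0.44). The adipocyte median was -0.31 (camera adjusted p = 0.0806). Of 10 liver genes, none passed the test (0 adjusted over the list alone), with a median of 2.65 (camera adjusted p = 0.483) that was -1.29 without Model 2. Albumin (Alb), named after its values were seen, stood at 3842 CPM in Model 2, 422 CPM in Control 1 and between 25.2 and 120 CPM in the other 4 libraries. Of 9 skeletal muscle genes, 1 rose (1 adjusted over the list alone), Neb, the giant muscle protein nebulin, with 3.39 (SE 0.43), and the list had a median of 1.99 (adjusted p = 0.293). Of 12 Schwann cell and nerve genes, 1 fell (1 adjusted over the list alone), the neurotrophin receptor gene Ngfr with -2.51 (SE 0.56). Camera called that list lower (median -0.72, adjusted p = 0.0164, adjusted p = 0.363 with an estimated correlation), and likewise the list of 6 cardiac muscle genes (median -1.88, adjusted p = 0.0151, adjusted p = 0.225 with an estimated correlation), of which none passed the gene test (0 adjusted over the list alone). No member passed the test, over all genes or adjusted over the list alone, among 10 mesothelial genes (median 1.44, adjusted p = 0.483), 3 kidney tubule genes (-0.51, adjusted p = 0.703), 6 adrenal cortex genes (-0.30 with a positive test, adjusted p = 0.977) or 2 exocrine pancreas genes (-0.21, too few for camera). Without Model 1 the liver count was 3. Ngfr lost its call without Control 1, Control 2, Model 1 or Model 2 (adjusted p from 0.0510 to 0.104), and the Schwann count was 0 without Control 1, Control 2 or Model 2. The Schwann list lost its own without Control 1, Control 2 or Model 3 (0.181, 0.113 and 0.161), and the cardiac list without Model 3 (0.110).

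Some genes of fibrinolysis rose, and so did the anticoagulant receptor gene Thbd. Of 13 tested fibrinolysis genes, 4 rose and none fell (5 adjusted over the list alone). Among them, Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133 of GRCm38) rose by 3.34 (SE 0.30) and Plat, tissue plasminogen activator, by 2.72 (SE 0.44, adjusted p = 0.00389). Anxa2, outside the naming rule and chosen after the values were seen, rose by 1.02. Plau, the urokinase gene, had a log2 fold change of 0.90 (SE 0.70, adjusted p = 0.609). Camera gave the list a median of 1.09 and an adjusted p of 6.93e-05 (adjusted p = 0.175 with an estimated correlation). Of 13 anticoagulant genes, 1 rose (3 higher and 1 lower adjusted over the list alone): Thbd, thrombomodulin, from 61.1 ± 11 to 190 ± 69.8 CPM (1.64, SE 0.31, adjusted p = 0.00957). Procr, the endothelial protein C receptor gene, had a log2 fold change of 1.13 (SE 0.45, adjusted p = 0.225) and Tfpi, tissue factor pathway inhibitor, 0.76 (SE 0.64, adjusted p = 0.638). The list had a median of 0.46 and a camera adjusted p of 0.0524. Plat lost its call without Control 1 and Model 2 together (adjusted p = 0.0717).

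Among 17 coagulation factors and receptors, 1 rose and 1 fell (2 and 1 adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 0.114). F5, coagulation factor V, rose from 22.2 ± 11.7 to 333 ± 150 CPM (3.91, SE 0.46, adjusted p = 4.50e-04). F8, coagulation factor VIII, went from 153 ± 103 to 22.1 ± 6.48 CPM (-2.79, SE 0.46, adjusted p = 0.00459). F3, which encodes tissue factor, the cellular starter of coagulation, had a log2 fold change of -1.35 (SE 0.97, adjusted p = 0.566). Vwf, von Willebrand factor, had 0.79 (SE 0.25, adjusted p = 0.114). Both F5 and F8 kept their calls in each of 14 alternative settings.

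Some cytokine and chemokine genes rose, while others did not pass the test. Of 16 inflammatory cytokine genes, 7 rose and none fell (7 adjusted over the list alone), with a median log2 fold change of 2.23. Il1b, interleukin 1 beta, rose from 3.49 ± 4.10 to 51.2 ± 9.96 CPM (3.87, SE 0.90, adjusted p = 0.0304). Of 23 chemokine genes, 8 rose and none fell (11 higher and 1 lower adjusted over the list alone), median 0.77, and 10 of the 23 had negative fold changes. Cxcl3 rose by 6.21 (SE 0.81) and Cxcl5 by 7.31 (SE 1.63), both ligands of the neutrophil receptor CXCR2. By camera the cytokine list had an adjusted p of 3.51e-07 (adjusted p = 0.231 with an estimated correlation) and the chemokine list 0.00221 (adjusted p = 0.254 with an estimated correlation). Il1b lost its call without Control 2 or any 1 of the Model libraries (adjusted p from 0.0641 to 0.0802) and Cxcl5 without any 1 Control library or Model 3 (0.0538 to 0.145). The cytokine count was 4 without Model 3.

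Of 19 leukocyte adhesion genes, 3 rose and 1 fell (4 and 2 adjusted over the list alone). Selp, which encodes P-selectin of platelets and endothelium, rose from 11.8 ± 4.14 to 147 ± 20.5 CPM (3.64, SE 0.37, adjusted p = 1.68e-04), and the integrin gene Itgam of myeloid cells by 2.10 (SE 0.35). The third was Cd44, from 137 to 387 CPM, outside the naming rule. Jam3, a junctional adhesion molecule, was lower with -1.87 (SE 0.48, adjusted p = 0.0496). Sele, E-selectin, had a log2 fold change of 3.13 (SE 1.60, adjusted p = 0.375) at a mean of 6.08 CPM in Model. The list had a median of -0.20, a positive mean of 0.24 and a camera adjusted p of 0.560. Jam3 lost its call without any 1 Control library, Model 2 or Model 3 (adjusted p from 0.0698 to 0.152). The lower count was 0 without Control 2, Control 3, Model 2 or Model 3, and 2 without Model 1.

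Camera called none of 3 lists of innate effector systems, which does not show them unchanged. Of 13 genes of neutrophil extracellular traps and the oxidative burst, 1 rose and 1 fell (1 and 3 adjusted over the list alone). The lower gene was Dnase1l3, which encodes a secreted DNase, with -1.69 (SE 0.44, adjusted p = 0.0498). That list had a median of 0.24 and a camera adjusted p of 0.992, with the test leaning lower. Of 18 inflammasome and pyroptosis genes, 1 rose, Il1b (1 higher and 1 lower adjusted over the list alone), median 0.38 (camera adjusted p = 0.122). Of 21 complement genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of -0.29, a mean of 0.06 and a camera adjusted p of 0.977. C5ar1, the receptor of the fragment C5a, rose by 2.76 (SE 0.70, adjusted p = 0.0480), besides Itgam and C4b (1.29, outside the naming rule), and Cd55, which shields cells from complement, had a log2 fold change of -1.62 (SE 0.28). Dnase1l3 lost its call without Control 1, Control 3, Model 1 or Model 3 (0.116 to 0.222), and C5ar1 without Control 2, Control 3, Model 2 or Model 3 (0.0676 to 0.369). The higher trap and burst count was 0 without any 1 library but Model 3, and the lower one 0 without Control 1, Control 3, Model 1 or Model 3, 3 without Control 2 and 2 without Model 2. The higher inflammasome count was 0 without Control 2 or any 1 of the Model libraries, and the lower one was 1 without Control 2. The higher complement count was 1 without Control 2, Control 3 or Model 3.

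Some genes of hypoxia and glycolysis and of the interferon response rose. Of 26 tested hypoxia and glycolysis genes, 11 rose and none fell (19 adjusted over the list alone), with a median log2 fold change of 1.26. Slc16a3, a lactate exporter, went from 4.89 ± 3.08 to 135 ± 43.1 CPM (4.78, SE 0.53, adjusted p = 2.76e-04), and Adm, the vasodilator peptide adrenomedullin, rose by 3.97 (SE 0.47). Of 23 interferon response genes, 10 rose and none fell (17 adjusted over the list alone), median 1.66. Rsad2, the antiviral protein viperin, rose by 3.42 (SE 0.41) and Oas3, an oligoadenylate synthetase, by 3.40 (SE 0.76). By camera the hypoxia list had an adjusted p of 3.22e-13 (adjusted p = 0.175 with an estimated correlation) and the interferon list 1.14e-10 (adjusted p = 0.225 with an estimated correlation). The hypoxia count was 7 without Control 3 and 7 without Model 1. The interferon count was 6 without Control 1, 4 without Control 2, 4 without Model 1 and 1 without Model 2, and Oas3 lost its call without Model 1 (adjusted p = 0.0727) or Model 2 (adjusted p = 0.0893).

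Of 18 matrix proteases and inhibitors, 9 rose and none fell (11 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 1.58. Mmp8, the collagenase of neutrophils, rose by 6.39 (SE 0.65), besides Timp1. Of 21 matrix and wound proteins, 7 rose and 2 fell (8 and 4 adjusted over the list alone). Lox, which crosslinks collagen and elastin, rose from 40.6 ± 11 to 520 ± 153 CPM (3.68, SE 0.32), and Spp1, osteopontin, by 3.35 (SE 0.64). Eln, elastin, had a log2 fold change of -1.87 (SE 0.29) and Col5a1, a fibrillar collagen, one of -0.97 (SE 0.25). By camera the protease list had an adjusted p of 3.55e-06 (adjusted p = 0.225 with an estimated correlation). The matrix list, with a median of -0.02 and a mean of 0.60, had 0.0585. Spp1 lost its call without Model 1 or Model 3 (adjusted p = 0.0575 and 0.0604), and Col5a1 without any 1 library (adjusted p from 0.0661 to 0.185), which left a lower count of 1 in each case.

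Of 24 immediate early genes, 6 rose and none fell (8 adjusted over the list alone), with a median log2 fold change of 0.32, led by the AP-1 gene Fosl1 with 6.01 (SE 1.01) and Ier3 with 3.64 (SE 0.51). Of 20 heat shock and unfolded protein response genes, 4 rose and none fell (6 adjusted over the list alone), median 0.69. They were the inducible chaperone gene Hspa1b with 4.81 (SE 0.77), which may share reads with Hspa1a, the stress-induced gene Sesn2 with 2.78 (SE 0.59), and, outside the naming rule, Hspb1 from 46.8 to 188 CPM and Hspa5 from 453 to 1691 CPM. Of 17 heme and iron genes, 4 rose and none fell (9 adjusted over the list alone), median 0.94. Lcn2, a siderophore-binding protein of neutrophils and inflamed tissue, rose from 20.7 ± 7.47 to 1211 ± 453 CPM (5.87, SE 0.41, adjusted p = 2.06e-05) and Slc39a14, a zinc and iron importer, by 3.78 (SE 0.31). The haptoglobin gene Hp rose by 3.17 and Slc7a11, a cystine transporter, by 1.98, both outside the naming rule. Camera gave the immediate early list an adjusted p of 0.00534 (adjusted p = 0.379 with an estimated correlation), the heat shock list 2.03e-04 (adjusted p = 0.303 with an estimated correlation) and the heme list 4.72e-08 (adjusted p = 0.187 with an estimated correlation). Without Control 2 the immediate early list was not called (adjusted p = 0.138). Sesn2 lost its call without Control 2, Model 1 or Model 2 (adjusted p = 0.0691, 0.0781 and 0.0991). With limma-voom the calls of Fosl1, Hspa1b and Sesn2 were lost (adjusted p = 0.150, 0.0865 and 0.0673).

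None of 22 proliferation genes passed the gene test (0 adjusted over the list alone). Camera called the list lower (median -0.48, adjusted p = 0.0353, adjusted p = 0.534 with an estimated correlation), and the call was lost without Control 1, Control 3, Model 1 or Model 3 (0.267, 0.0749, 0.0539 and 0.112). No member passed the gene test, over all genes or adjusted over the list alone, among 81 genes of the nuclear-encoded respiratory chain (median -0.11, adjusted p = 0.309), 5 mitochondrially encoded mRNAs (-1.14, adjusted p = 0.0585) or 77 ribosomal protein genes (0.12, adjusted p = 0.0525). Without Model 3, 3 mitochondrially encoded mRNAs were lower. Of 44 long non-coding RNAs on a further list, 1 matched a row of the table, with a log2 fold change of 0.21 (SE 0.71, adjusted p = 0.940), and the list was too small for camera. Of the 18 lists that camera called, 12 higher and 6 lower, none was called with an estimated correlation between genes.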

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

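The fit without both Control 1 and Model 2 was chosen after the data were seen; the other settings were planned. Against 566 changed genes (377 higher, 189 lower), leaving out 1 library at a time gave 317 to 440 (221 to 312 higher, 92 to 136 lower), with fewer samples to test. The fit without both libraries gave 285 (222 and 63). Without a filter 1111 genes were called (642 and 469) over 17761 tested, and DESeq2 called 1217 (639 and 578). Limma-voom called 115 lower genes. The cause of these shifts was not tested. RLE and upper-quartile scaling, the stricter filter and a required log2 fold change of at least 1 gave 553, 557, 566 and 556 genes. Each of the 566 genes kept its sign wherever it was tested, 563 of them under the stricter filter. The replicate number as a block gave 575 genes and kept 496 of the 566. Same-numbered libraries deviated together with correlations of 0.147, 0.119 and 0.004, and Control 3 and Model 3 correlated best with other numbers, so the numbers were not taken as pairs. Of 12 lists higher and 6 lower by camera, 0 and 0 were called with an estimated correlation. In place of camera, fry called 11 higher and 1 lower, not all of them the same lists. It called matrix and wound proteins (fry adjusted p = 0.0155), but not the immediate early (0.0739) or heat shock (0.0742) lists. Its only lower list was that of B cells, and T and NK cell (0.068) and smooth muscle (0.107) genes were not called. Leaving out 1 library, camera called 11 to 16 higher and 5 to 6 lower. Of 70 named genes past the test, 34 kept their calls in every setting. Direction reversed in some setting for 13 results, none past its threshold in the main test or when reversed, and the cause was not tested. Leaving out 1 library, their median log2 fold changes spanned -0.20 to 0.00 (endothelial), -0.67 to 0.02 (fibroblast), 0.13 to 2.98 (skeletal muscle), -1.29 to 3.88 (liver), -1.62 to 0.75 (kidney tubule), -0.25 to 1.53 (adrenal cortex), -0.39 to 0.00 (adhesion), 0.01 to 0.41 (extracellular traps), -0.49 to 0.11 (complement), -0.37 to 0.06 (respiratory chain) and -0.04 to 0.26 (ribosomal proteins), with -0.31 to 0.15 for the gene Pecam1. Without Control 1 and Model 2, reversed values were 0.85 (mesothelial), -0.73 (liver), 1.16 (kidney tubule), 0.26 (extracellular traps), -0.39 (complement) and 0.15 (Pecam1). The others were endothelial with upper-quartile scaling (-0.10), no filter (-0.08), the stricter filter (-0.06) and limma-voom (-0.05), skeletal muscle with no filter (1.02), adrenal cortex with the stricter filter (-0.32) and limma-voom (0.21), extracellular traps with the block (0.16) and complement with fry (-0.29). A list's direction is that of its set test, which can differ in sign from its median. In simulated counts the test called 43.0% of 4-fold changes planted in genes above a set mean count, so a gene that did not pass was not shown to be unchanged.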

Other observations

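The pathway test, the additional gene lists and the tests of explanations below were chosen after the results were seen, except the count of sample splits. Among 279 annotated pathways tested in each direction over 5134 genes, 17 were over-represented among higher and 20 among lower genes (hypergeometric test with Benjamini-Hochberg adjustment). Many of the 20 shared the lower genes H2-Aa, H2-Ab1, H2-DMa, H2-DMb2 and H2-Ob, so they are not separate findings. Asthma, graft-versus-host disease, allograft rejection and type I diabetes mellitus had no other lower genes. Antigen processing and presentation held 11 lower genes of 63, against 1.3 expected (adjusted p = 6.59e-06). They include Ciita, the master regulator of MHC class II genes, with a log2 fold change of -2.27 (SE 0.29), the class II genes H2-Ab1 with -2.12 (SE 0.31) and H2-Aa with -1.40 (SE 0.29), and Cd74, the invariant chain, which went from 1336 ± 410 to 428 ± 32.9 CPM (SD, n = 3 each). The 11 also include the T cell genes Cd4, Cd8a and Cd8b1, and B cells, which express class II genes, had lower marker genes as well (median -1.55), so the pathway is not separate from the lymphocyte lists. Among higher genes, ECM-receptor interaction held 14 of 77 (adjusted p = 6.12e-05), 5 of them members of the platelet list (Gp1ba, Gp6, Gp9, Itga2b and Itgb3), and Jak-STAT signaling 14 of 112 (adjusted p = 0.00237).

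Of 15 lipogenic genes, 8 fell and none rose by edgeR's quasi-likelihood test, with a median log2 fold change of -2.16. The list had no set test, and the annotated pathways fatty acid biosynthesis (2 of 12 lower, adjusted p = 0.190) and fatty acid metabolism (3 of 47, adjusted p = 0.375) did not pass. Regulation of lipolysis in adipocytes did pass the hypergeometric test (5 of 50 lower, adjusted p = 0.048). Fasn, fatty acid synthase, went from 6629 ± 4265 to 605 ± 195 CPM (-3.45, SE 0.54, adjusted p = 0.00307) and Acly, ATP citrate lyase, from 1454 ± 999 to 293 ± 20.3 CPM. Of 20 acute-phase genes, again without a set test, 11 rose and none fell, median 3.35. Serpina3n, a protease inhibitor of a family whose reads may be shared, rose from 134 ± 11 to 2299 ± 663 CPM, and the metallothionein gene Mt2 from 36.6 ± 22.2 to 1046 ± 246 CPM.

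The real split gave 566 changed genes and the highest of the other 9 splits of the 6 libraries gave 0, so 1 of 10 splits gave as many. With 10 splits no share under 0.05 can be reached. At an unadjusted p under 0.05, edgeR gave 2200 genes for the real split and 263 to 641 for the others.

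Lymphocyte lists were lower while neutrophil, platelet and erythroid lists were higher. Dilution of wall RNA by thrombus RNA is not the whole fall, since it would lower wall genes about as much as B cell genes (median -1.55, upper quartile -1.26), and the endothelial median was -0.05 (lower quartile -0.45). A part of it stays open, since the smooth muscle median was -0.61, with 17 of 18 genes negative, and the fibroblast median -0.45. More lymph node tissue in the Control samples, which would also hide B cell transcripts brought by circulating blood, cannot be told apart from a change in lymphocytes, since 10 genes of lymph node stroma and high endothelium had a median of -0.80 (-0.55 without Control 1, -1.83 without Model 1) but quartiles of -1.97 and 0.51, with Ccl21a lower and Cxcl13 higher. A selective gain of granulocytes, platelets and red cells in the thrombus with loss of lymphocytes after ligation may also contribute and was not tested.

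Of the 15 lipogenic genes, 8 were lower in Model. Less fat tissue as the only cause would lower other adipocyte genes alike. The median of 15 of them was -0.31, above the lipogenic upper quartile of -0.92. The lipogenic list was chosen after the results were seen, which favours such a gap, so the comparison cannot decide this. These genes were uneven, with 10 negative and 5 positive fold changes and quartiles of -0.78 and 0.37. Adrb3 had a log2 fold change of -3.34, and the pathway regulation of lipolysis in adipocytes was over-represented among lower genes. Less fat tissue therefore stays open, as a part or as the whole of the fall. A single library was not the source, since the highest median with 1 library left out was -1.69. The ligation, the feeding state and the surgery also remain open as causes and were not tested.

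Of the 20 acute-phase genes, 11 were higher in Model. Liver tissue in Model 2 is not the source of the whole rise, since without Model 2 the acute-phase median was 3.61 while the liver median was -1.29. Neutrophils carrying these transcripts cannot be told apart from induction in other cells. The acute-phase genes had a median log2 ratio of -0.60 in Model 2 against Model 1 and Model 3 (quartiles -0.98 and 0.94), and the neutrophil list 1.34 (quartiles 0.53 and 1.62). Induction after ligation remains open and was not tested.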
